A study of Mus musculus with 22 samples.

How the data were processed

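CUT&RUN libraries from mouse embryonic stem cells (ESC) and neural progenitor cells (NPC) were compared for 5 antibodies: SUZ12, JARID2, MTF2, H3K27me3 and H3K4me3. Each antibody had 2 libraries per cell type, which the series describes as biological replicates, and IgG had 1 library per cell type, so 22 libraries were used and no column was left out. The deposited values are counts: whole numbers of reads per window of 5000 bp centred on 1 annotated transcription start site (TSS) per gene, with no normalization. Per the submitters' processing notes, reads were aligned to mm10 with Bowtie2 2.3.4.3 and Picard 2.19 was used in a role that was not stated. The counting program, read filters and handling of duplicate reads are not given in the sources used here. Drosophila spike-in material was added to the samples, but no spike-in count or library total was used here, so a change common to all TSSs of an antibody was not measured.

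The table held 24467 windows, of which 5370 (21.9%) overlapped another window and 66 were identical to another, so that neighbouring genes can share reads. No read was counted in 142 windows. Gene symbols that a spreadsheet had turned into dates (27) were restored from their transcripts, and 24284 transcripts were found in the RefSeq table, 23375 of them with the same symbol. Depth was taken as the total count over the TSS windows of a library. It ran from 298458 (IgG in ESC) to 8425292 counts (H3K4me3 in NPC), and 3 counts corresponded to 10.05 and 0.356 CPM (counts per 1e6 counts of the library) in those libraries. Reads copied by PCR are not independent molecules, so such floors cover counting error only.

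Changes between NPC and ESC were tested per antibody over its 4 libraries with edgeR 4.0.16 quasi-likelihood tests (R 4.3.3), TMM scaling and filterByExpr at a minimum count of 10. Differences between antibodies in that change were tested as interaction terms over 8 libraries. Enrichment over IgG was tested in a joint fit of the 22 libraries and called at a log2 fold of at least 1, with the single IgG library of a cell type assumed to vary like the other groups. A TSS was called at a Benjamini-Hochberg adjusted p below 0.05 throughout, and adjusted p-values of single TSSs below come from edgeR. TSSs with H3K4me3 and H3K27me3 called above IgG in the same cell type were counted as carrying both marks. Fold changes are log2 NPC over ESC with the standard error (SE) of the fit, and levels are mean CPM with the standard deviation (SD) of 2 libraries. A log2 ratio to IgG used a prior count of 2. Correlations of changes were taken across TSSs with Pearson's r and Spearman's rho.

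There were 22 gene lists: naive pluripotency, primed epiblast, neural progenitor, SHH response and ventral neural tube, neuronal differentiation, dorsal neural tube and neural crest, forebrain, glia, the HoxA, HoxB, HoxC and HoxD clusters, mesoderm, endoderm, surface ectoderm and trophectoderm, germline, WNT, BMP and FGF ligands, imprinted genes, PRC2 subunits, PRC1 subunits, housekeeping and olfactory receptors. Each was tested against the other TSSs for each antibody (110 tests) with camera (limma 3.58.1) at a preset correlation of 0.01, and again with an estimated correlation and with fry. The genes named are those of a fixed rule. It takes landmarks (among them Nanog, Klf4, Pou5f1, Sox1, Pax6, Olig2, Nkx2-2, Hoxd13, Gata6, T and Actb) and the member of each list with the smallest p if it passed. It adds the 5 passing genes with the largest change in each direction whose replicates did not overlap and whose average signal was at or above the median, leaving out predicted, small RNA and olfactory receptor genes. For interactions it takes the last part alone, or the 5 smallest p-values in each direction where none passed. The groups, comparisons, lists, naming rule and first set of alternatives were chosen before the data were examined.

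Alternatives were DESeq2 1.42.0, scaling by library totals, TMM factors from background TSSs, no filter, a minimum count of 30, TSSs left out where IgG itself differed more than 2-fold, a replicate block, 1 fit over all libraries, each library left out in turn, a log2 fold over IgG of at least 2, IgG of both cell types together and a rule without a model. Others were added after seeing the data: non-overlapping windows (21631), fits of 1 antibody with IgG only, a crossed replicate block, and the 2 NPC JARID2 libraries summed. Those 2 libraries differed by no more than sampling noise (chi-square per degree of freedom 0.998), and they were kept apart because the labels list them as replicates. Simulated data of the same depths had 1 common dispersion per fit for all TSSs and no difference in enrichment between replicates. The tests were tried on these data, and may recover more or fewer changes in real libraries. At a log2 fold of 1 they recovered 40.6% of changed SUZ12 TSSs, 15.6% for JARID2, 9.2% for MTF2, 4.2% for H3K27me3 and 92.9% for H3K4me3, and at a log2 fold of 2 they recovered 85.9%, 81.1%, 80%, 71.8% and 99%. Interactions with a log2 difference of 2 were recovered in 34.3% (JARID2 minus MTF2), 47.5% (JARID2 minus SUZ12), 40.4% (MTF2 minus SUZ12) and 21% (H3K27me3 minus SUZ12) of cases, and a log2 fold of 2 over IgG for SUZ12 in ESC in 60%. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.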

Results

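CUT&RUN, in which a nuclease tethered to an antibody releases the DNA around a bound protein or histone mark, was run on mouse ESC kept in 2i/LIF medium and on NPC made from them. The NPC were treated with bFGF at 10 ng/mL for 72 h and then with SAG, an agonist of the Hedgehog pathway, at 500 nM for 48 h. SUZ12 is a core subunit of the Polycomb complex PRC2, which methylates histone H3 at lysine 27. JARID2 and MTF2 are accessory subunits of different PRC2 forms, PRC2.2 and PRC2.1. H3K27me3 is the product of PRC2, and H3K4me3 marks active and poised promoters. There were 2 libraries for each antibody in each cell type and 1 IgG library per cell type. Total counts over the 24467 TSS windows ran from 448667 to 857691 for SUZ12, from 339591 to 492529 for JARID2, from 439379 to 832117 for MTF2, from 647615 to 1569812 for H3K27me3 and from 3264267 to 8425292 for H3K4me3. The IgG libraries had 298458 counts in ESC and 667898 in NPC. The labels state 2 biological replicates, and the p-values of changes and interactions measure the spread between these libraries. An interaction fit gives its 2 antibodies 1 shared spread per TSS, which can understate that of the noisier antibody. The p-values of gene lists rest on a preset correlation of 0.01, and those over IgG on an assumed spread of the single IgG library per cell type. The comparisons ask which TSSs gained or lost each PRC2 subunit and each mark between ESC and NPC.

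In NPC, H3K4me3 fell at the genes of naive pluripotency and rose at neural progenitor genes. Of 21 naive pluripotency TSSs 20 fell and 0 rose. At Nanog, a pluripotency transcription factor (window 122704988 to 122709988 on chromosome 6), the level fell from 300.1 ± 4.13 to 12.5 ± 4.09 CPM (SD, n = 2), a log2 change of -4.46 ± 0.11 (SE). Pou5f1, which encodes OCT4, fell by 4.26 ± 0.11 on the log2 scale (adjusted p = 1.16e-305). Of 24 neural progenitor TSSs 19 rose and 2 fell (Lhx2 and Sox2). At Sox1, an early neural transcription factor, H3K4me3 rose from 54.2 ± 2.08 to 127 ± 0.477 CPM, a log2 change of 1.24 ± 0.09, and at Meis1, a homeobox gene, by 2.84 ± 0.09. The SHH response and ventral neural tube list had 11 TSSs that rose and 2 that fell among 17, and Nkx2-2, a ventral patterning factor whose window overlaps a neighbour's, rose by 2.90 ± 0.11. The 2 that fell were Olig1 and Olig2, genes of motor neuron and oligodendrocyte progenitors. The Hox clusters, which pattern the body axis, divided within HoxB: Hoxb1, Hoxb2, Hoxb3, Hoxb4 and Hoxb7 rose while Hoxb5, Hoxb6, Hoxb9 and Hoxb13 fell. Hoxa2 rose by 2.18 ± 0.10 in a shared window and 9 of 11 HoxA TSSs fell, Hoxc4 rose and 8 of 9 HoxC TSSs fell, and 8 of 9 HoxD TSSs fell. Of 20 forebrain TSSs 14 fell. The largest changes among other genes were Elavl4, a neuronal RNA-binding protein, at 4.86 ± 0.17 and AU018091 at -4.52 ± 0.13.

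Against all other TSSs, H3K4me3 was lower in NPC for the naive pluripotency list (median log2 -3.20, adjusted p = 1.31e-11 by camera) and higher for the neural progenitor (1.28, 3.35e-08) and SHH (0.49, 0.000269) lists. It was also lower for HoxA (median -1.44, adjusted p = 0.00197), HoxC (-1.37, 0.00479), HoxD (-1.24, 0.000414), dorsal neural tube and neural crest (-0.57, 0.0207; 3 rose and 12 fell of 17) and forebrain (-0.62, 0.00572). Mesoderm (-0.73, 0.0193; 6 rose and 17 fell of 29), surface ectoderm and trophectoderm (-0.61, 0.00531; 1 and 11 of 16), germline (-1.37, 0.000611; 1 and 11) and housekeeping genes (-0.32, 0.00770; 2 and 16 of 25) were lower too. These 12 calls had an adjusted p = 0.441 to 0.622 with an estimated correlation. The lists that did not pass were primed epiblast (5 rose, 7 fell), glia (2 and 6), HoxB, endoderm (4 and 8), WNT, BMP and FGF ligands (12 and 18), imprinted genes (9 and 7), PRC2 subunits (2 and 4), PRC1 subunits (8 and 5) and olfactory receptors (1 and 20 of 130). The last passed as higher without ESC replicate 2 (adjusted p = 3.24e-06) or NPC replicate 2 (1.78e-07) and as lower without NPC replicate 1 (0.00269). Neuronal differentiation did not pass either (14 rose and 11 fell of 34): its median was -0.09 while its mean was 0.44 and its test pointed up. Counts adjusted over the list alone differed for forebrain (4 rose, 15 fell), HoxD (0 and 9), endoderm (4 and 10), PRC2 subunits (2 and 5), housekeeping (3 and 16) and olfactory receptors (0 and 16). Over all genes H3K4me3 changed at 11064 of 19776 TSSs, rising at 5286 and falling at 5778, whereas DESeq2 found 6934. With TMM factors from background TSSs the count was 6053, the median of all TSSs moved from -0.02 to 0.20, and the medians of primed epiblast, endoderm, WNT, BMP and FGF ligands, PRC2 subunits and neuronal differentiation turned positive. The calls of dorsal neural tube (adjusted p = 0.0950) and housekeeping genes (0.377) were then lost, and falls numbered 4 for dorsal neural tube, 2 for housekeeping, 6 for forebrain and 4 for surface ectoderm. Both calls were also lost without NPC replicate 1 (0.0705 and 0.108). With background factors neuronal differentiation passed as higher (adjusted p = 0.00127; 14 rose and 3 fell) and glia as lower (0.0454).

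**Figure D1:**
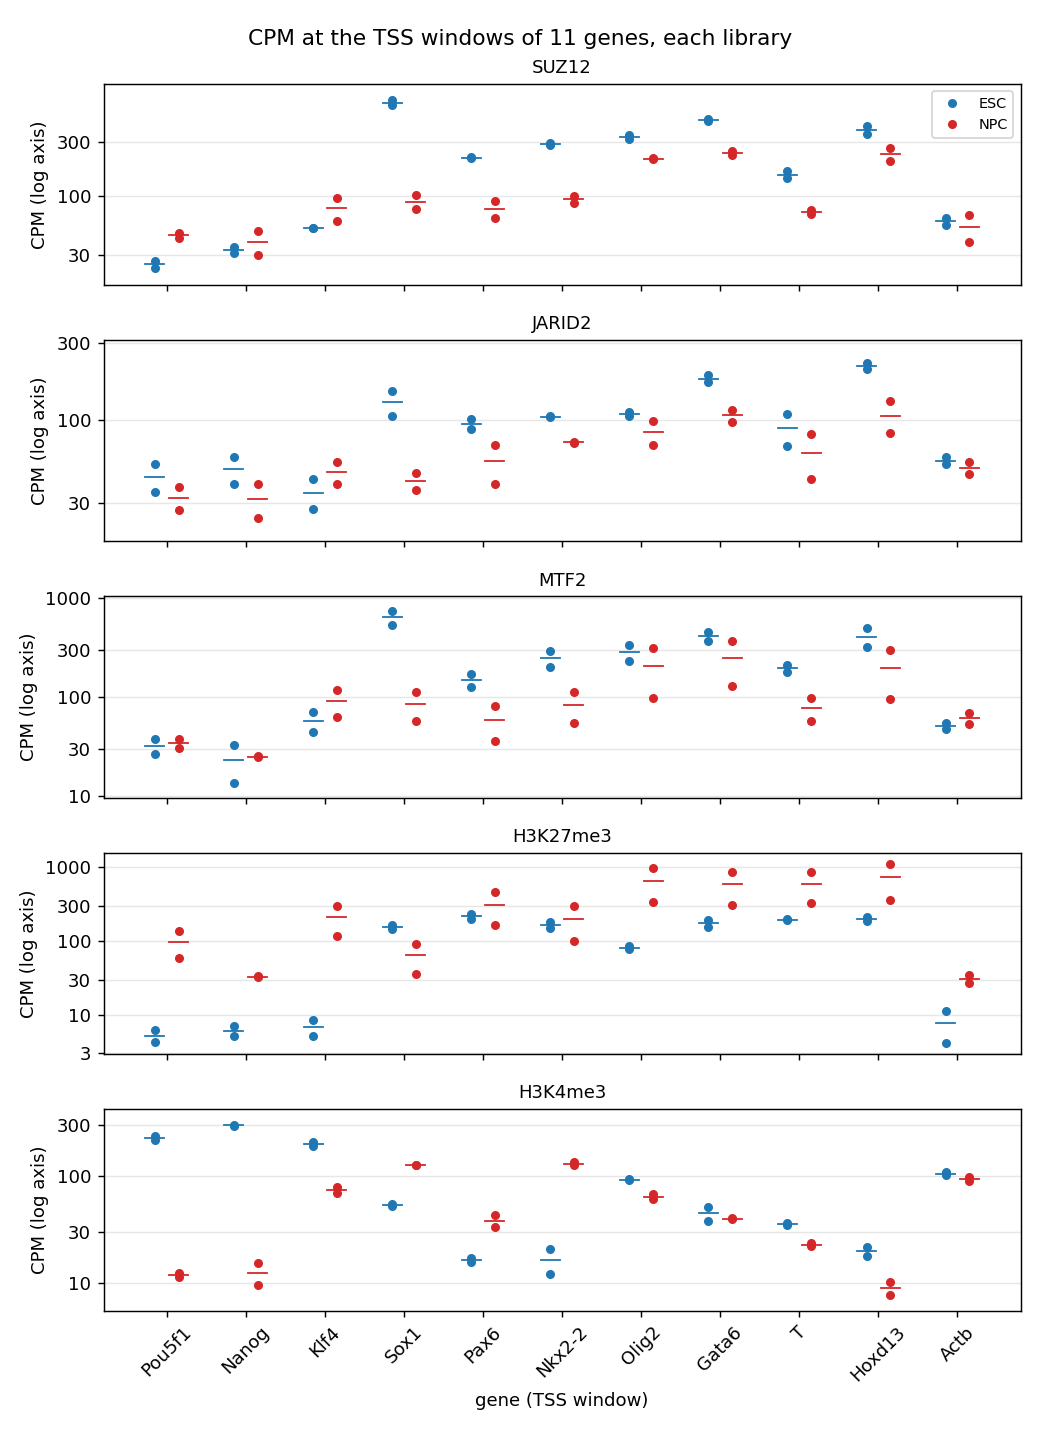
Levels in CPM (log axis) at the TSS windows of 11 landmark genes, with 1 panel per antibody, 1 point per library (2 ESC, 2 NPC) and a line at each mean. Sox1 shows SUZ12 falling from 662 to 88.8 CPM and H3K4me3 rising from 54.2 to 127 CPM, while Pou5f1 shows H3K27me3 rising from 5.20 to 97.6 CPM; the H3K4me3 fall at Actb (-0.20) became 0.04 with factors from background TSSs, and the SUZ12 falls at Olig2 and Hoxd13 became 0.21 and 0.12 at a minimum count of 30.

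H3K27me3 rose in NPC at the same group of pluripotency genes. Of 20 naive pluripotency TSSs tested 16 rose and 0 fell, while among 24 neural progenitor TSSs 6 fell (Cdh2, Fabp7, Meis2, Pou3f4, Prom1 and Sox1) and 2 rose (Hes1 and Sox2). At Pou5f1 the level rose from 5.20 ± 1.36 to 97.6 ± 56.1 CPM (SD, n = 2), a log2 change of 4.17 ± 0.46, and passed from 2.22 log2 units below IgG (log2 -2.22) to 2.00 above it. Klf4, a naive pluripotency factor, rose by 4.94 ± 0.71. Nanog rose by 2.44 ± 0.44 but was not called above IgG in NPC (log2 0.40). These ESC levels rested on few counts, since 3 counts made 3.11 and 4.63 CPM in the ESC libraries. Sox1 fell by 1.27 ± 0.55 (adjusted p = 0.0447), and Pax6, a neural progenitor factor, gave 0.53 ± 0.86 (adjusted p = 0.626). Zic5, a zinc finger gene of the epiblast and dorsal neural tube, rose by 5.99 ± 1.09, from 7.52 ± 3.36 to 472 ± 322 CPM, and Fgf4, an FGF ligand made by ESC, by 5.55 ± 1.14. The largest falls were at Gramd3 (-2.86 ± 0.43), Zfp287 (-2.70 ± 0.45) and Gpr165 (-2.68 ± 0.36). Hoxd13 gave 1.88 ± 1.18 (adjusted p = 0.177).

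The naive pluripotency list was higher for H3K27me3 than other TSSs (median 2.88, camera adjusted p = 2.28e-09), and so were the HoxA (2.03, 0.000281), HoxB (1.48, 0.0276), HoxC (1.75, 0.00137) and HoxD (1.83, 0.00264) clusters. Forebrain (1.67, 1.44e-05; 2 rose, 0 fell), dorsal neural tube and neural crest (1.54, 0.000125; 4 and 0), neuronal differentiation (1.39, 0.00213; 4 and 5), primed epiblast (1.38, 0.0130; 6 and 3), mesoderm (1.24, 0.00756; 2 and 3) and WNT, BMP and FGF ligands (0.95, 0.00232; 6 and 3) were also higher. PRC2 subunits (2.12, 0.00541; 7 of 9 rose), PRC1 subunits (0.98, 0.0202; 9 rose and 2 fell of 21) and housekeeping genes (1.248, 0.000611; 12 and 1 of 20) were higher as well, yet Actb, which rose by 2.07 ± 0.43, stayed below IgG in NPC (log2 -0.65). The medians of PRC2 subunits (-0.22 and -0.46) and housekeeping genes (-0.32 and -0.57) were below IgG in both NPC libraries, and 0 PRC2 subunits rose with DESeq2. Germline genes (-0.84, 0.00572; 0 rose and 9 fell of 19) and olfactory receptors (-0.61, 1.35e-09; 4 and 299 of 911) were lower. These 16 calls had an adjusted p = 0.447 to 0.678 with an estimated correlation. Lists that did not pass were neural progenitor (median -0.62, adjusted p = 0.149), SHH response (0.79, 0.115; 4 rose, 1 fell), endoderm (1.37, 0.0514; 2 and 3), surface ectoderm and trophectoderm (1.20, 0.601; 3 and 5), glia (-0.37, 0.345; 1 and 3) and imprinted genes (-0.28, 0.484; 3 and 6). Counts adjusted over the list alone differed for primed epiblast (6 rose, 4 fell), neural progenitor (2 and 4), SHH (3 and 0), neuronal differentiation (3 and 5), dorsal neural tube (1 and 0), forebrain (0 and 0), mesoderm (1 and 2), WNT, BMP and FGF ligands (4 and 2), housekeeping (14 and 1) and olfactory receptors (4 and 275). In all, H3K27me3 rose at 5017 and fell at 5127 of 21863 TSSs, and each list median kept its sign under both other scalings. The counts per list did not: with library totals they were 3 rose and 12 fell for neural progenitor genes, 15 and 3 for neuronal differentiation, 14 and 4 for mesoderm, 13 and 0 for forebrain, 12 and 1 for dorsal neural tube, 8 and 3 for primed epiblast and 13 and 3 for the ligands. Of the Hox TSSs 10, 2, 5 and 5 rose in HoxA, HoxB, HoxC and HoxD with library totals, against 1, 0, 0 and 0 with TMM, while 2 PRC2 subunits and 2 housekeeping genes rose. DESeq2 gave 16 and 2 for neuronal differentiation. Olfactory receptors fell at 141 TSSs with library totals, 638 with background factors and 107 with DESeq2. Without NPC replicate 2 the neural progenitor list passed as lower (adjusted p = 0.000518). Endoderm passed as higher with background factors (0.0378), without ESC replicate 1 (0.0217) and without NPC replicate 1 (0.000427), and SHH without ESC replicate 1 (0.0301) or NPC replicate 1 (0.00159). Without NPC replicate 2 the list calls of HoxB (adjusted p = 0.588), primed epiblast (0.145), neuronal differentiation (0.156), mesoderm (0.414), WNT, BMP and FGF ligands (0.554) and PRC1 subunits (0.0909) were lost. Those of HoxB (0.0916), mesoderm (0.0571) and PRC1 subunits (0.0594) were also lost without ESC replicate 2, and that of HoxB with non-overlapping windows (0.0636). The split was 1678 and 4533 with library totals and 1499 and 8639 with background factors, which moved the median of all TSSs from 0.12 to -0.04 and -0.61, and DESeq2 called 939 and 2776. The 2 NPC libraries held 11.04% and 19.61% of their counts in the top 1% of TSSs, and without ESC replicate 1 the count of 10144 was 3574.

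**Figure D2:**
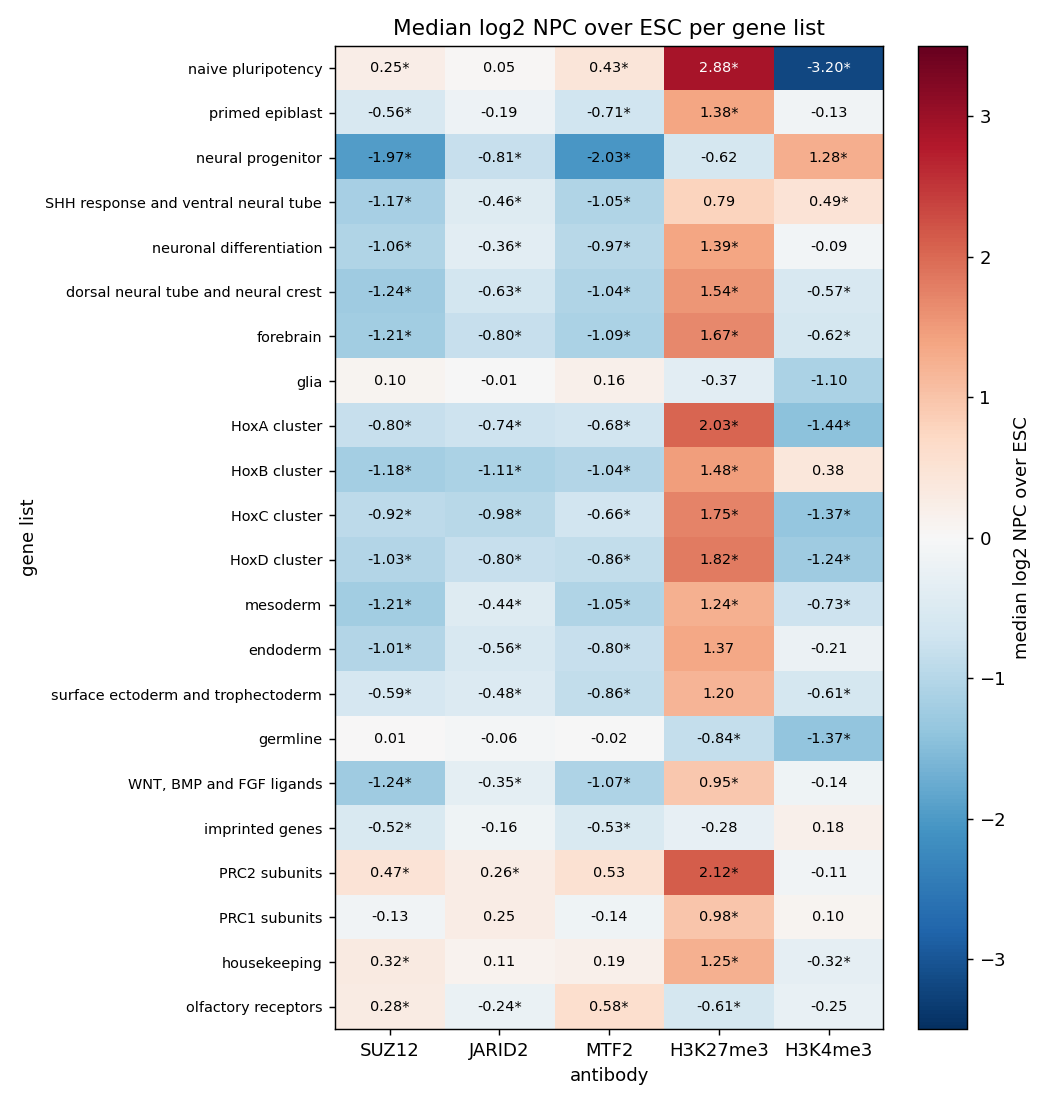
Median log2 NPC over ESC of each of the 22 gene lists (vertical) for each of the 5 antibodies (horizontal), with colour and number giving the median and an asterisk a camera adjusted p below 0.05 at the preset correlation. Naive pluripotency shows 2.88 for H3K27me3 and -3.20 for H3K4me3, and neural progenitor shows -1.97 for SUZ12. Medians that change sign with library totals, background factors or DESeq2 are those of glia, germline and PRC1 subunits for SUZ12 and MTF2, glia for JARID2, housekeeping for MTF2, and primed epiblast, neuronal differentiation, endoderm, WNT, BMP and FGF ligands and PRC2 subunits for H3K4me3. List medians were not compared at a minimum count of 30, where HoxA kept 94.9% to 115.9% of its SUZ12 excess over IgG.

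SUZ12 fell at developmental genes of nearly every lineage listed. The median log2 fall was largest at neural progenitor genes. A larger share of TSSs fell in HoxA, HoxB, HoxC, HoxD, forebrain, dorsal neural tube, endoderm and the WNT, BMP and FGF ligands. Of 24 neural progenitor TSSs 17 fell and 0 rose. At Sox1 (window 12393018 to 12398018 on chromosome 8) SUZ12 fell from 662 ± 48.9 to 88.8 ± 18.6 CPM (SD, n = 2), a log2 change of -2.90 ± 0.24 (adjusted p = 2.59e-28), and Pax6 fell by 1.49 ± 0.23. Nkx6-1, a ventral neural tube factor, fell by 2.47 ± 0.23 with 11 of 17 TSSs of the SHH response list, and 22 of 33 neuronal TSSs tested fell (1 rose). Vax1 fell by 1.91 ± 0.22 with 17 of 20 forebrain TSSs, Lmx1a by 1.72 ± 0.23 with 13 of 17 dorsal neural tube TSSs, and the growth factor Fgf9 by 2.13 ± 0.23 with 30 of 40 WNT, BMP and FGF ligands (2 rose). Outside the nervous system, the vascular receptor gene Kdr fell by 1.85 ± 0.24 with 20 of 29 mesoderm TSSs, Prox1 by 2.25 ± 0.23 with 14 of 19 endoderm TSSs, and Gata3 by 1.58 ± 0.22 in a shared window with 8 of 16 surface ectoderm TSSs (2 rose). Of the Hox TSSs, 10 of 11 fell in HoxA, 8 of 10 in HoxB, 7 of 9 in HoxC and 9 of 9 in HoxD, and Hoxb2 fell by 1.77 ± 0.22. Cdkn1c, an imprinted cell cycle inhibitor, fell by 2.28 ± 0.24 with 9 of 23 imprinted TSSs (1 rose). The largest falls included clustered protocadherins, cell adhesion genes (Pcdha9, -3.39 ± 0.30), and Zfp536 (-2.93 ± 0.25). Of 19 naive pluripotency TSSs 5 rose (Fgf4, Klf2, Prdm14, Tbx3 and Tfcp2l1) and Esrrb fell, but 2 rose and 2 fell with background factors (median 0.01) and 1 rose and 1 fell with DESeq2. Tbx3 rose from 104 ± 12.7 to 316 ± 1.07 CPM (1.58 ± 0.22), and Zic5 rose by 1.87 ± 0.24. Pou5f1 (0.87 ± 0.35, adjusted p = 0.0686), Klf4 (0.58 ± 0.25, 0.101) and Nanog (0.25 ± 0.33, 0.699) did not pass.

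Camera placed SUZ12 below other TSSs for neural progenitor (median -1.97, adjusted p = 1.08e-17), SHH (-1.17, 1.28e-08), neuronal differentiation (-1.06, 1.63e-09), dorsal neural tube (-1.24, 2.73e-09), forebrain (-1.21, 3.92e-12) and WNT, BMP and FGF ligands (-1.24, 3.54e-15). Mesoderm (-1.21, 1.82e-10), endoderm (-1.01, 5.52e-07), surface ectoderm and trophectoderm (-0.59, 0.0124), primed epiblast (-0.56, 0.0149; 2 rose, 7 fell) and imprinted genes (-0.52, 0.000139) were lower, as were HoxA (-0.80, 3.84e-05), HoxB (-1.18, 2.92e-06), HoxC (-0.92, 0.000175) and HoxD (-1.03, 1.77e-06). Naive pluripotency (0.25, 0.0188), PRC2 subunits (0.47, 0.0450; Mtf2 rose and Phf19 fell), housekeeping genes (0.32, 0.0309; 2 rose) and olfactory receptors (0.28, 2.70e-05; 14 rose and 1 fell of 423) were higher, and of the last 61 rose with library totals, 6 rose and 3 fell with background factors and 0 passed with DESeq2. These 4 lists lay near or below IgG. Their median log2 ratio to IgG, as a mean of 2 libraries, was -0.22 in ESC and 0.28 in NPC for naive pluripotency. It was 0.099 and -0.025 for PRC2 subunits, -0.015 and -0.041 for housekeeping genes and -0.43 and -0.13 for olfactory receptors. Several list calls rested on single libraries: naive pluripotency was lost without NPC replicate 1 (adjusted p = 0.112), PRC2 subunits without ESC replicate 1 (0.0741) or NPC replicate 2 (0.0635), and primed epiblast without ESC replicate 1 (0.0749). Housekeeping was lost without ESC replicate 1 (0.0663), ESC replicate 2 (0.0517) or NPC replicate 2 (0.0821). These 19 calls had an adjusted p = 0.441 to 0.537 with an estimated correlation. None of the 79 calls over the 5 antibodies held with it, but that test has only 2 residual degrees of freedom. Glia (0 rose, 2 fell), germline (1 and 2) and PRC1 subunits (1 and 6, with Cbx2 at -1.96 ± 0.23) did not pass, and their medians (0.10, 0.01 and -0.13) changed sign under another scaling. Adjusted over the list alone, the counts were the same for neural progenitor, HoxB, HoxD, endoderm, PRC2 subunits and housekeeping, and elsewhere they were 7 rose and 1 fell for naive pluripotency, 2 and 8 for primed epiblast, 0 and 13 for SHH, 1 and 23 for neuronal differentiation, 0 and 14 for dorsal neural tube and 0 and 19 for forebrain. They were 2 and 2 for glia, 0 and 11 for HoxA, 0 and 8 for HoxC, 2 and 21 for mesoderm, 3 and 8 for surface ectoderm, 2 and 2 for germline, 2 and 32 for WNT, BMP and FGF ligands, 1 and 10 for imprinted genes, 2 and 7 for PRC1 subunits and 1 and 0 for olfactory receptors. In total SUZ12 changed at 3416 of 21238 TSSs (630 rose, 2786 fell), of which 18.4% were higher, against 55.9% with library totals and 4.11% with background factors, which moved the median of all TSSs from 0.07 to 0.34 and -0.17. The count was 1767 with DESeq2 (11 rose, 1756 fell) and 1619 at a minimum count of 30 (888 rose, 731 fell, so that rises were the majority, as with library totals), where Olig2 (-0.62) and Hoxd13 (-0.71) turned to 0.21 and 0.12. It was 2115 without ESC replicate 1, 2263 without NPC replicate 1 and 2242 without NPC replicate 2.

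**Figure D3:**
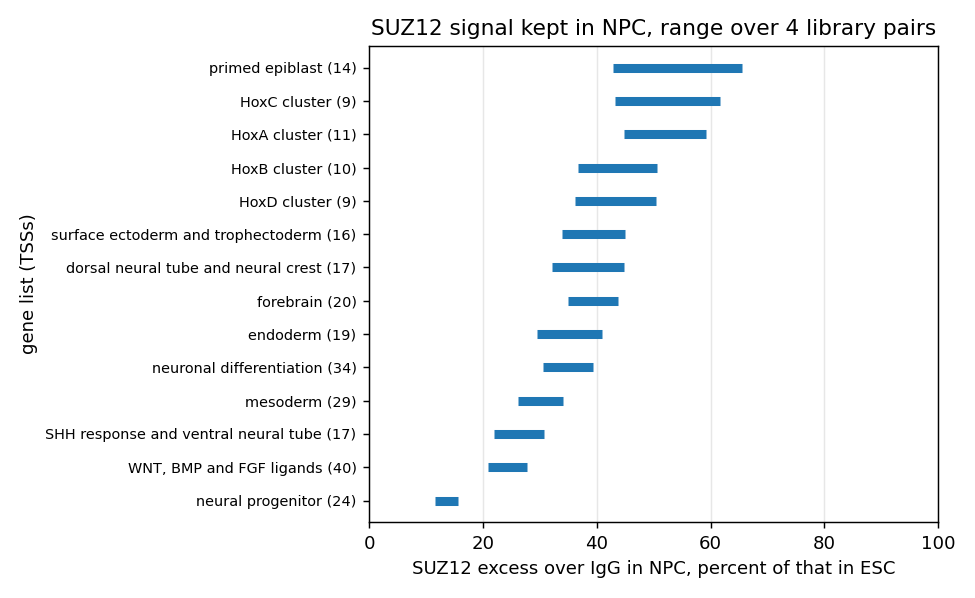
SUZ12 excess over IgG in NPC as a percentage of that in ESC (horizontal) for the 14 lists shown, with the number of TSSs in parentheses and bars from the lowest to the highest of 4 library pairs. The neural progenitor list kept 11.6% to 15.5% and the HoxA cluster 44.8% to 59.2%. With the SUZ12 libraries scaled at a minimum count of 30 these were 31.7% to 38.5% and 94.9% to 115.9%.

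JARID2 changed at far fewer TSSs, and most of these fell. Of 180 changed TSSs among 21456 tested, 163 fell and 17 rose. Tbx5, a heart and forelimb factor, fell from 147 ± 9.92 to 38.2 ± 2.38 CPM (SD, n = 2), a log2 change of -1.93 ± 0.28 (adjusted p = 1.62e-07). Meis2 (-1.80 ± 0.28), Nkx2-1 (-1.76 ± 0.22), Pax7 (-1.67 ± 0.23) and Sox1 (-1.61 ± 0.28) also fell. Hoxc11 fell by 1.68 ± 0.21 and, in shared windows, Hoxd11 by 1.74 ± 0.22 and Hoxb6 by 1.45 ± 0.20, and JARID2 fell at 5 of 11 HoxA, 7 of 10 HoxB, 6 of 9 HoxC and 3 of 9 HoxD TSSs. It fell at 9 of 23 neural progenitor, 8 of 20 forebrain, 7 of 29 mesoderm, 6 of 33 neuronal, 5 of 17 dorsal neural tube, 4 of 19 endoderm, 3 of 17 SHH and 3 of 16 surface ectoderm TSSs and 2 of 39 WNT, BMP and FGF ligands, with 0 rising in each. Zic2, in a shared window (1.65 ± 0.32), and Tbx3 (1.43 ± 0.31) rose, as 1 primed epiblast and 1 naive pluripotency gene. The fall was also present at Grb10 (-1.21 ± 0.25) among imprinted genes and Cbx8 (-0.96 ± 0.22) among PRC1 subunits.

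By camera, JARID2 was lower for HoxB (median -1.11, adjusted p = 5.79e-12), HoxC (-0.98, 2.61e-10), HoxD (-0.80, 5.95e-08), HoxA (-0.74, 2.82e-07), forebrain (-0.80, 3.90e-13), neural progenitor (-0.81, 1.83e-07) and dorsal neural tube (-0.63, 6.93e-08). Mesoderm (-0.44, 4.53e-10), endoderm (-0.56, 1.77e-06), neuronal differentiation (-0.36, 3.00e-06), SHH (-0.46, 3.13e-05), WNT, BMP and FGF ligands (-0.35, 5.63e-05), surface ectoderm (-0.48, 0.000328) and olfactory receptors (-0.24, 4.93e-08) were lower and PRC2 subunits higher (0.26, 0.0277; 0.0627 without ESC replicate 1). Against IgG, PRC2 subunits had a median log2 ratio of -0.26 in ESC and 0.0082 in NPC, and olfactory receptors 0.034 and -0.080. All 15 list calls had an adjusted p = 0.441 to 0.447 with an estimated correlation. Naive pluripotency, primed epiblast, glia, germline, imprinted genes, PRC1 subunits and housekeeping genes did not pass, and for glia the median was -0.01 while its mean was 0.03 and its test pointed up. Adjusted over the list alone, JARID2 fell at 8 HoxA (1 rose), 8 HoxB, 7 HoxC, 6 HoxD, 12 neural progenitor, 13 forebrain, 11 mesoderm, 10 neuronal, 8 dorsal neural tube, 8 endoderm, 6 SHH and 4 surface ectoderm TSSs and 5 ligands. Naive pluripotency passed as higher without ESC replicate 1 (adjusted p = 0.0231) and imprinted genes as lower without ESC replicate 2 (0.0299). DESeq2 called 96 TSSs and 1 fit over all 22 libraries called 0, and the count was 102 without ESC replicate 1, 67 without ESC replicate 2 and 117 without NPC replicate 2.

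MTF2 fell along with SUZ12. At Pcdha9 it fell from 149 ± 20.8 to 20.0 ± 1.5004 CPM (SD, n = 2), a log2 change of -2.89 ± 0.43 (adjusted p = 6.55e-08). Zfp536 fell by 2.88 ± 0.90, the neural crest and glial factor Sox9 by 2.79 ± 1.00, Sox11 by 2.74 ± 0.52, Pou3f4 by 2.25 ± 0.37 and Pax6 by 1.33 ± 0.43 (adjusted p = 0.0235). Sox1 gave -2.92 ± 1.16 and did not pass (adjusted p = 0.0730). By edgeR with TMM, MTF2 fell at 11 of 23 neural progenitor TSSs, 9 of 39 WNT, BMP and FGF ligands (1 rose), 7 of 24 imprinted genes, 4 of 32 neuronal and 4 of 29 mesoderm TSSs, but at 0 of 39 Hox and 0 of 20 forebrain TSSs. DESeq2 called falls at 3 forebrain, 2 HoxB and 1 HoxD TSSs, and background factors at 1 HoxC TSS. MTF2 rose at the naive pluripotency gene Klf2 (1.97 ± 0.34), at Zic5 (1.72 ± 0.42) and at 48 of 384 olfactory receptors (107 with library totals, 10 with background factors, where 3 fell, and 0 with DESeq2). Camera placed neural progenitor (median -2.03, adjusted p = 3.49e-16), WNT, BMP and FGF ligands (-1.07, 4.69e-14), forebrain (3.01e-09), neuronal differentiation (-0.97, 8.27e-09), mesoderm (-1.05, 3.35e-08), dorsal neural tube (-1.04, 5.95e-08) and SHH (-1.05, 7.57e-08) below other TSSs. Endoderm (-0.80, 1.21e-05), HoxB (-1.04, 2.30e-05), HoxD (-0.86, 0.000280), HoxA (-0.68, 0.00117), HoxC (-0.66, 0.00548), imprinted genes (-0.53, 0.00263), surface ectoderm (-0.86, 0.0112) and primed epiblast (-0.71, 0.0191) were lower, and naive pluripotency (0.43, 0.0276) and olfactory receptors (0.58, 1.92e-13) higher. The median log2 ratio to IgG of olfactory receptors stayed below 0, at -0.63 in ESC and -0.059 in NPC. For naive pluripotency it was -0.098 and 0.28. Without NPC replicate 1 the calls of HoxA (adjusted p = 0.547), HoxC (0.549), HoxD (0.144), surface ectoderm (0.239) and primed epiblast (0.623) were lost, and the share of the excess over IgG kept in NPC was 19.7% to 109.5% for HoxA and 21.4% to 113.4% for HoxC over the library pairs. Primed epiblast (0.103) and HoxC (0.0573) were also lost without ESC replicate 1, and naive pluripotency without ESC replicate 2 (0.257) or NPC replicate 2 (0.391). The adjusted p of these 17 was 0.447 to 0.625 with an estimated correlation, and glia, germline, PRC2 subunits, PRC1 subunits and housekeeping genes did not pass. Adjusted over the list alone, MTF2 fell at 15 neural progenitor TSSs, 18 ligands, 9 imprinted genes, 8 mesoderm and 4 primed epiblast TSSs and 0 of the SHH list, where 1 fell over all TSSs. MTF2 changed at 2568 of 20885 TSSs, rising at 681 and falling at 1887. The split was 2343 and 1391 with library totals and 125 and 3385 with background factors, which moved the median of all TSSs from 0.07 to 0.38 and -0.29, and DESeq2 called 5 and 1565. The top 1% of TSSs held 3.05% and 7.02% of counts in the 2 NPC libraries, and the count was 99 without NPC replicate 1, 217 without ESC replicate 1 and 983 at a minimum count of 30, where rises outnumbered falls (604 and 379). Without NPC replicate 2 PRC1 subunits passed as lower (adjusted p = 0.0256).

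Falls were shared between SUZ12 and MTF2 and between SUZ12 and JARID2. Among TSSs tested for both, 1379 fell for SUZ12 and MTF2, against 258 expected of independent lists, and 156 of the 162 TSSs with lower JARID2 also had lower SUZ12 (22 expected). MTF2 and JARID2 fell together at 18 TSSs (15 expected). The number was 27 with background factors (28 expected), 21 with library totals (11 expected) and 22 with DESeq2 (19 expected). By edgeR with TMM, falls of MTF2 were called at 0 of the Hox and forebrain TSSs although its medians fell there too. DESeq2 called such falls at 3 forebrain, 2 HoxB and 1 HoxD TSSs. SUZ12 fell and H3K4me3 rose at 1326 TSSs (748 expected), and H3K27me3 rose and H3K4me3 fell at 2239 (1451 expected; 1088 and 471 expected with library totals, 366 and 217 with background factors, 625 and 205 with DESeq2). SUZ12 and H3K27me3 fell together at 388 TSSs (637 expected) and rose together at 292 (143 expected), while SUZ12 fell and H3K27me3 rose at 209 (690 expected) and the reverse held at 83 (132 expected). These depended on scaling: with library totals SUZ12 fell with H3K27me3 at 505 (429 expected) and against its rise at 335 (164 expected), and joint rises were 257 (193), or 50 (11) with background factors and 10 (2) with DESeq2. The NPC change of JARID2 was then tested against that of SUZ12 and MTF2 as an interaction. JARID2 minus SUZ12 differed at 1135 TSSs (1041 positive, 94 negative) and JARID2 minus MTF2 at 782 (631 and 151). At a minimum count of 30 most were negative (241 positive and 458 negative, and 93 and 316), as were those of JARID2 minus MTF2 with library totals (315 and 544). The log2 changes of JARID2 started from a low enrichment. The share of its excess over IgG kept in NPC was 16.8% to 21.7% for neural progenitor genes, 37.2% to 57.5% for HoxA and 26.7% to 37.0% for HoxB, against 11.6% to 15.5%, 44.8% to 59.2% and 36.7% to 50.5% for SUZ12. The SUZ12 shares of neural progenitor genes and HoxA were 17.0% to 21.4% and 59.0% to 73.8% with library totals. At a minimum count of 30 they were 31.7% to 38.5% and 94.9% to 115.9%. Epha7, an ephrin receptor gene of the nervous system, had the largest difference in both, at 3.28 ± 0.55 (adjusted p = 3.91e-06) and 3.101 ± 0.68 (0.00354), from a log2 change of 0.82 for JARID2, -2.39 for SUZ12 and -2.21 for MTF2. Efna5, a ligand of such receptors, differed by 2.93 ± 0.69 between JARID2 and MTF2, and Cdh2 by 2.99 ± 0.53 between JARID2 and SUZ12, with Klf2 (-1.83 ± 0.49) and Il21r (-1.94 ± 0.48) on the other side. MTF2 minus SUZ12 differed at 0 TSSs by edgeR and at 0 by DESeq2, with 1133 at an unadjusted p under 0.05, and its smallest adjusted p was 0.747, shared by Nkapl (-1.65 ± 0.43) and Coil (1.56 ± 0.44). H3K27me3 minus SUZ12 differed at 7258 TSSs (3926 and 3332; 1943 and 3820 with library totals, 1338 and 4821 with background factors), with Cpt1a (5.02 ± 0.79), Fgf4 (4.72 ± 0.96) and Axl (-3.46 ± 0.68) among the largest.

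The size of these interaction counts depended on single libraries and on scaling. With library totals the positive and negative counts were 315 and 544 for JARID2 minus MTF2, 455 and 298 for JARID2 minus SUZ12 and 1943 and 3820 for H3K27me3 minus SUZ12. The median over all TSSs moved from 0.01 to -0.33, from 0.02 to -0.27 and from 0.29 to -0.13, and with background factors to 0.28, 0.18 and -0.17. With background factors they were 1539 and 65, 1676 and 67, and 1338 and 4821, and the MTF2 minus SUZ12 median moved from 0.03 to -0.11. DESeq2 gave 196, 388 and 3577 TSSs in the same order. For JARID2 minus MTF2 the count was 138 and 83 without ESC JARID2 replicate 1 or 2, 41 and 193 without NPC JARID2 replicate 1 or 2, 170 and 1858 without ESC MTF2 replicate 1 or 2, and 127 and 1254 without NPC MTF2 replicate 1 or 2. For JARID2 minus SUZ12 it was 620 and 640 without ESC JARID2 replicate 1 or 2, 329 and 755 without NPC JARID2 replicate 1 or 2, 730 without ESC SUZ12 replicate 1, and 741 and 613 without NPC SUZ12 replicate 1 or 2. For H3K27me3 minus SUZ12 it was 3332 without ESC H3K27me3 replicate 1, 3995 without ESC SUZ12 replicate 1, and 4295 and 4036 without NPC SUZ12 replicate 1 or 2. MTF2 minus SUZ12 had 1 TSS without ESC MTF2 replicate 2 or NPC MTF2 replicate 2.

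**Figure D4:**
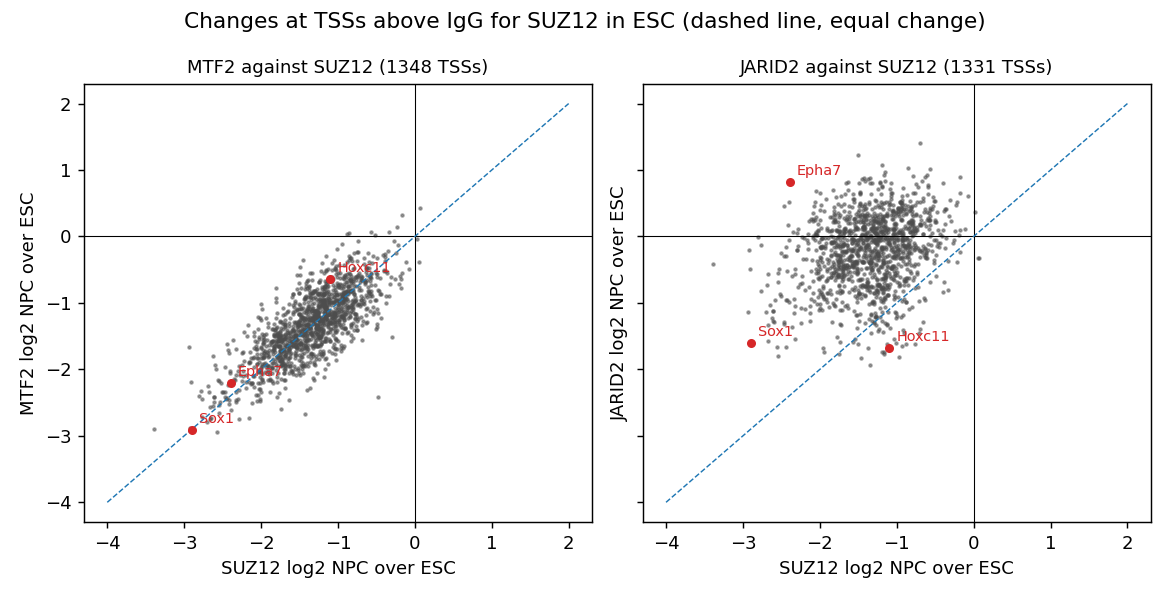
Log2 NPC over ESC of MTF2 (left, 1348 TSSs) and JARID2 (right, 1331 TSSs) on the vertical axis against that of SUZ12 on the horizontal axis, 1 point per TSS above IgG for SUZ12 in ESC, with a dashed line of equal change. MTF2 lies along the line and JARID2 mostly above it, with Epha7 at 0.82 for JARID2 and -2.39 for SUZ12. The MTF2 median over all TSSs was 0.07, against 0.38 with library totals and -0.29 with background factors.

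In ESC, SUZ12 and MTF2 were called above IgG at developmental genes, whereas neither was called at any TSS in NPC by the fit over 22 libraries. SUZ12 was nonetheless higher than IgG in NPC as a list median, with a mean log2 ratio over the 2 libraries of 2.49 for HoxC, 2.28 for HoxA and 1.99 for forebrain, and 363 TSSs were called when SUZ12 was fitted with IgG only, a fit added after seeing the data. SUZ12 was above IgG at 1349 TSSs and MTF2 at 2130, with 1303 shared (121 expected of independent lists), and part of that excess may come from the single IgG library that both were compared with. In libraries simulated without enrichment for either antibody 0 TSSs had both calls. This does not measure what the shared IgG library adds where TSSs are enriched. SUZ12 was above IgG at 16 of 24 neural progenitor TSSs, 17 of 20 forebrain TSSs, 8 of 11 HoxA, 8 of 10 HoxB, 9 of 9 HoxC and 8 of 9 HoxD TSSs. Of the 1349, which were chosen from the ESC libraries that also enter the change, SUZ12 fell at 1251 in NPC (median -1.31), MTF2 at 715 of 1348 tested (-1.32) and JARID2 at 128 of 1331 (-0.17). H3K27me3 rose at 103 and fell at 173 of them (median 0.31), and H3K4me3 rose at 719 and fell at 309 (0.28). The count of 0 in NPC compares with 495 TSSs for SUZ12 and 651 for MTF2 at an unadjusted p under 0.05, and with 410 and 275 by a rule without a model (log2 ratio to IgG of at least 1 in both replicates). JARID2 was above IgG at 0 TSSs in either cell type by the fit over 22 libraries (in ESC at 38 with library totals, 16 with background factors and 188 when fitted with IgG only), with 560 in ESC and 141 in NPC at an unadjusted p under 0.05 and 759 and 120 by the rule without a model. Without ESC SUZ12 replicate 1 the ESC count was 439, without ESC MTF2 replicate 1 it was 585, and without NPC MTF2 replicate 1 the NPC count was 38.

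H3K4me3 was above IgG at 8570 TSSs in ESC and 9278 in NPC, and H3K27me3 at 5374 and 3598. TSSs carrying both marks are known as bivalent and are typical of developmental genes in ESC. There were 549 in ESC and 964 in NPC, fewer than the 1932 and 1400 expected of independent lists. Data simulated without enrichment gave 0, which does not measure the part due to a shared IgG library. Part of any such overlap may come from the shared IgG library. The 549 were found among 23836 TSSs tested. They included 5 of 24 neural progenitor, 2 of 20 forebrain, 2 of 29 mesoderm, 1 of 34 neuronal, 0 of 10 HoxB and 0 of 9 HoxD TSSs. The share was thus above that of all TSSs in the neural progenitor, forebrain and mesoderm lists, although most members were outside the set. H3K27me3 alone was called in ESC at 13, 17, 24, 24, 10 and 9 TSSs of these lists. Of the 549, 203 (37.0%) kept both marks in NPC, 207 (37.7%) had H3K4me3 alone, 98 (17.9%) had H3K27me3 alone and 41 (7.47%) had neither. Of 17 naive pluripotency TSSs with H3K4me3 alone in ESC 0 had it alone in NPC and 6 had H3K27me3 alone, and the number of the list's 21 TSSs above IgG for H3K27me3 was 1 in ESC and 13 in NPC. For the 24 neural progenitor TSSs the number above IgG for H3K4me3 was 8 in ESC and 19 in NPC, and for H3K27me3 it was 18 and 12. Housekeeping genes carried H3K4me3 alone at 24 of 25 TSSs in ESC and 23 in NPC, with 0 above IgG for H3K27me3. Of 4825 TSSs with H3K27me3 alone in ESC 1883 had it alone in NPC and 2350 had neither mark. At the 8021 TSSs with H3K4me3 alone in ESC, H3K27me3 rose at 3697 and fell at 77 (median 1.07; 843 and 40 with library totals, 1216 and 588 with background factors and 411 and 9 of 1583 tested with DESeq2), yet 217 had H3K27me3 alone in NPC and 276 had both marks. This class was chosen by the lack of an H3K27me3 call in the ESC libraries that also enter the change, which favours rises. The bivalent counts in ESC and NPC were 63 and 140 with library totals, 3002 and 3139 with background factors and 92 and 136 at a log2 fold of at least 2. The ESC count stayed below that expected of independent lists in each setting (3319 with background factors). The NPC count passed it with background factors (2190 expected) and with each antibody fitted with IgG only, a setting chosen after seeing the data (177, 131 expected). In that setting ESC had more such TSSs (342) than NPC, H3K27me3 was above IgG in NPC at 376 TSSs, and 22 of the 342 kept both marks while 216 had H3K4me3 alone. With background factors 2003 of 3002 kept both and 686 had H3K4me3 alone.

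**Figure D5:**
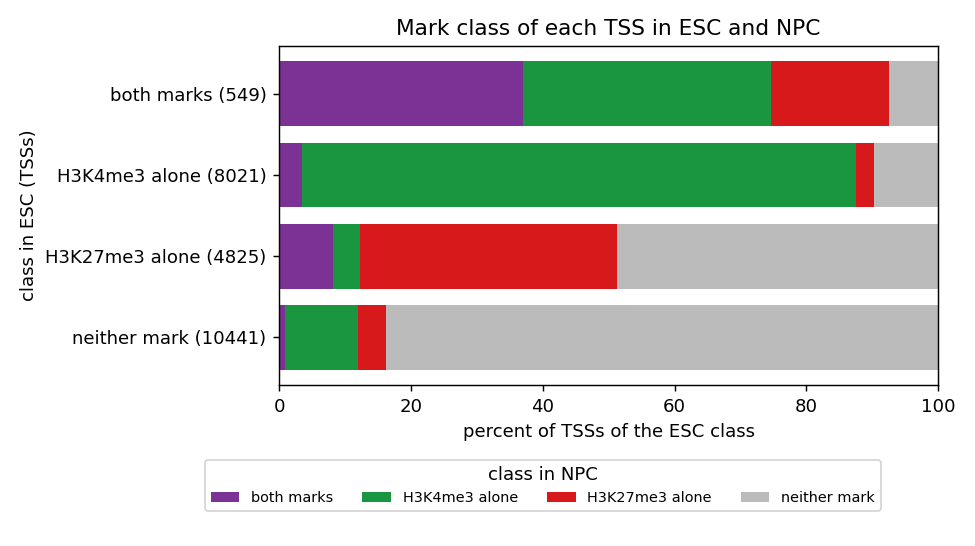
Percentage of TSSs (horizontal) of each ESC class (vertical, number of TSSs in parentheses) that fell into each class in NPC, by whether H3K4me3 and H3K27me3 were called above IgG. Of the 549 TSSs with both marks in ESC 37.0% kept both and 37.7% had H3K4me3 alone; with background factors 2003 of 3002 kept both, and with each antibody fitted with IgG only 22 of 342.

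Across TSSs above IgG for SUZ12 or H3K27me3, the changes of SUZ12 and MTF2 were correlated (Pearson's r = 0.83, Spearman's rho = 0.83), whereas those of SUZ12 and JARID2 (0.19, 0.13) and of MTF2 and JARID2 (0.13, 0.10) were only weakly so. Log2 levels of the 2 JARID2 libraries correlated at 0.63 in both ESC and NPC (0.87 and 0.71 for SUZ12). Noise of this size lowers r, so the weak values do not show that JARID2 changed apart from SUZ12. H3K4me3 changes were negatively correlated with those of H3K27me3 (-0.31, -0.23) and of SUZ12 (-0.29, -0.29), and H3K27me3 with SUZ12 (-0.16, -0.32). TSSs are not independent replicates, and no p-value is given for these 6 pairs. From replicate 1 or replicate 2 alone, r for SUZ12 and MTF2 was 0.775 and 0.573, and over all tested TSSs that of SUZ12 and H3K27me3 was 0.0819 in place of -0.16.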

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

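The tests of explanations below were all chosen after the results they address had been seen, while the interaction tests were planned.

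The change between NPC and ESC differed between antibodies by a test of the difference itself, an interaction term: at 782 TSSs between JARID2 and MTF2, at 1135 between JARID2 and SUZ12, and at 7258 between H3K27me3 and SUZ12. The first 2 rest on log2 changes, which are smaller where the enrichment over IgG is low: JARID2 was called above IgG in ESC at 0 TSSs by the fit over 22 libraries (188 when fitted with IgG only). At neural progenitor genes it kept more of its excess over IgG than SUZ12 (16.8% to 21.7% against 11.6% to 15.5%), but not at HoxB (26.7% to 37.0% against 36.7% to 50.5%). The order at neural progenitor genes depended on scaling. With SUZ12 alone rescaled, SUZ12 kept 17.0% to 21.4% there with library totals and 31.7% to 38.5% at a minimum count of 30. A smaller log2 change of JARID2 therefore does not by itself show that less of it was lost in every list. The direction also depended on the TSSs tested: most differences were positive (631 of 782 and 1041 of 1135), but at a minimum count of 30 most were negative (316 of 409 and 458 of 699).

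H3K27me3 was higher in NPC at housekeeping TSSs (12 of 20 rose; 2 with library totals and 4 with background factors) and at naive pluripotency TSSs (16 of 20; 14 and 12), although housekeeping genes are active in both cell types. If counts had been drawn to other TSSs in the ESC libraries, both lists would rise in NPC without passing the IgG background. At housekeeping TSSs the lower of the 2 NPC libraries had a median log2 ratio to IgG of -0.57 (ESC libraries -1.82 and -1.31), which is consistent with a shift that stayed below the background. At naive pluripotency TSSs the lower NPC library was at 1.44 (ESC -1.13 and -1.04), above IgG, which argues against this as the whole cause there. A gain of H3K27me3 at pluripotency genes during neural differentiation remains a hypothesis.

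SUZ12 was lower in NPC at 1251 of the 1349 TSSs bound in ESC, a share favoured by choosing them from the same ESC libraries; with TSSs chosen in 1 ESC library and measured from the other, the median log2 change was -1.04 to -0.82, but only -0.13 to -0.07 when scaled on TSSs at a minimum count of 30. A uniformly lower enrichment in the NPC libraries would leave the same share of the excess over IgG in every list, but the neural progenitor list kept at most 15.5% (11.6% to 15.5% over 4 library pairs) against 44.8% to 59.2% for HoxA, and 31.7% to 38.5% against 94.9% to 115.9% at a minimum count of 30, so it is not the whole cause. A part common to all TSSs stays open, since no spike-in count was used. Replacement of SUZ12 where H3K4me3 was gained stays open as well: where H3K4me3 fell, the median SUZ12 change was -1.02 to -0.80, but it reached -0.033 at a minimum count of 30, and it lay 0.12 to 0.21 above that where H3K4me3 rose. The scaling at a minimum count of 30 was set on TSSs with higher counts, so it can absorb a fall that those TSSs share. A loss of PRC2 binding that is deeper at neural progenitor genes may therefore underlie the unequal part.

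Chi-square per degree of freedom between the 2 NPC libraries was 6.67 for H3K27me3, 2.39 for H3K4me3 and 1.69 for MTF2, against 1.03 for SUZ12 and 0.998 for JARID2. At a given relative spread this value grows with depth, so it does not rank the antibodies by reproducibility. Log2 levels of the 2 NPC libraries correlated at 0.99 for H3K4me3, 0.91 for H3K27me3, 0.71 for SUZ12, 0.67 for MTF2 and 0.63 for JARID2. A difference in enrichment between 2 libraries predicts the same log2 ratio of excess over IgG in every list above IgG. This ratio of replicate 2 to replicate 1 was 1.64 to 1.86 over the 14 lists with a median log2 of at least 1 in both NPC libraries for H3K27me3 (SD 0.0660) and 1.69 to 2.16 over the 13 lists above 0.3 for MTF2 (SD 0.123); with the limits exchanged the SD was 0.115 for H3K27me3, with neural progenitor genes at 2.06 and germline genes at 1.54, and 0.0729 for MTF2. Both are consistent with a lower enrichment in replicate 1, whether from the assay or from the cells. ESC left among the NPC of replicate 1 would lower H3K27me3 there more at the naive pluripotency list than at the 39 Hox TSSs and so raise its ratio, but the ratio was 1.64 against 1.82 (difference -0.18), which argues against that for H3K27me3. A difference in how far the NPC cultures had differentiated was not tested.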

How the results depend on the processing

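The non-overlapping windows, crossed block, summed JARID2 libraries, fits of 1 antibody with IgG only, and background factors and joint IgG for bivalent TSSs were chosen after seeing the data; the other alternatives were planned. Of 312 alternative values of counts and correlations 180 stayed within the limits set, 131 moved and 1 reversed. Of 3155 values of named genes 2823 kept direction and call, 280 lost the call, 48 gained it and 4 reversed. Except where the construction shows it (fewer reads or TSSs, fewer libraries), the cause was not tested.

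With DESeq2 the changed TSSs were 1767 for SUZ12, 96 for JARID2, 1570 for MTF2, 3715 for H3K27me3 and 6934 for H3K4me3, and interactions were 196 (JARID2 minus MTF2), 388 (JARID2 minus SUZ12) and 3577 (H3K27me3 minus SUZ12). A minimum count of 30, which tests fewer TSSs, gave 1619 (SUZ12; 888 rose, 731 fell), 983 (MTF2; 604 and 379), 4698 (H3K27me3), 409 (JARID2 minus MTF2; 93 positive, 316 negative) and 699 (JARID2 minus SUZ12; 241 and 458). The majority direction of SUZ12, MTF2 and both interactions thus turned. TMM factors were then set on the TSSs kept, which have higher counts, so they can absorb a fall that those TSSs share. With SUZ12 so scaled HoxA kept 94.9% to 115.9% of its excess over IgG, against 44.8% to 59.2% with the main scaling. A minimum count of 30 also reversed SUZ12 at Olig2 (0.21) and Hoxd13 (0.12). Library totals gave 6211 for H3K27me3 and 753 for JARID2 minus SUZ12. Background TSS factors gave 6053 for H3K4me3, 1604 for JARID2 minus MTF2 and 1743 for JARID2 minus SUZ12, and reversed H3K4me3 at Actb (0.039). A single fit over 22 libraries gave 1615 for SUZ12, 0 for JARID2 and 6765 for H3K4me3. The planned choice of 1 TSS per gene left every TSS in, since each gene has 1.

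The replicate numbers did not pair the samples: deviations of equal numbers correlated at -0.005 to 0.01 for SUZ12 and JARID2 and below 0 elsewhere. With the replicate block MTF2 gave 510 and JARID2 minus MTF2 178, and with the crossed block MTF2 gave 4096.

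For TSSs above IgG, library totals gave 177 (NPC SUZ12), 38 (ESC JARID2), 204 (NPC MTF2), 2901 and 2129 (ESC and NPC H3K27me3) and 4371 and 4071 (H3K4me3). Background factors gave 146 (NPC SUZ12), 16 (ESC JARID2), 3430 and 175 (ESC and NPC MTF2) and 15359 and 14769 (H3K4me3). A log2 fold of at least 2 gave 860 (ESC SUZ12), 1148 (ESC MTF2), 2304 and 2139 (H3K27me3) and 3937 and 3624 (H3K4me3). IgG of both cell types together gave 2464 and 21 (SUZ12) and 3362 and 36 (MTF2). The rule without a model gave 410 (NPC SUZ12), 759 and 120 (JARID2), 275 (NPC MTF2), 3099 and 1855 (H3K27me3) and 4340 and 3666 (H3K4me3). Fits of 1 antibody with IgG only gave 2606 and 363 (SUZ12), 188 and 41 (JARID2), 1 (NPC MTF2) and 2655 and 376 (H3K27me3).

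Bivalent TSSs in ESC and NPC, then ESC ones with both marks, H3K4me3 alone, H3K27me3 alone and neither in NPC, numbered 63, 140, 11, 18, 12 and 22 with library totals and 3002, 3139, 2003, 686, 103 and 210 with background factors. At a log2 fold of at least 2 the first 5 were 92, 136, 17, 21 and 24. With IgG of both cell types 406 had both marks and 6 neither, and with 1 antibody and IgG only the numbers were 342, 177, 22, 216, 6 and 98.

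Of the 79 gene list calls 0 held with an estimated correlation, and fry gave 11. Over all tested TSSs the correlations were 0.725 (SUZ12 and MTF2), 0.134 (SUZ12 and JARID2), 0.0551 (MTF2 and JARID2), 0.0819 (SUZ12 and H3K27me3, reversed), -0.172 (H3K27me3 and H3K4me3) and -0.211 (SUZ12 and H3K4me3).

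With each library left out in turn, a lone library being assumed to vary like the other groups, changed TSSs were 2115 (without ESC replicate 1) to 3002 for SUZ12, 67 (without ESC replicate 2) to 129 for JARID2, 99 (without NPC replicate 1) to 2626 for MTF2, 3574 (without ESC replicate 1) to 10384 for H3K27me3 and 7811 to 12296 for H3K4me3. Interactions were 41 (without NPC JARID2 replicate 1) to 1858 (without ESC MTF2 replicate 2) for JARID2 minus MTF2, 329 (without NPC JARID2 replicate 1) to 1357 for JARID2 minus SUZ12, 0 to 1 for MTF2 minus SUZ12 and 3332 (without ESC H3K27me3 replicate 1) to 8374 for H3K27me3 minus SUZ12. TSSs above IgG were 439 (without replicate 1) to 1165 for ESC SUZ12, 585 (without replicate 1) to 2379 for ESC MTF2, 0 to 38 (without replicate 1) for NPC MTF2, 4036 to 5296 and 2676 to 4320 for ESC and NPC H3K27me3, 7675 to 7772 and 8144 to 9236 for H3K4me3, and 0 for NPC SUZ12 and JARID2. Gene list calls were 74 to 82. Correlations were 0.573 to 0.775, 0.131 to 0.146, 0.0849 to 0.0887, -0.213 to -0.0309, -0.462 to -0.212 and -0.332 to -0.203 in the order above. H3K27me3 at Nkx2-2 (0.28, not passing) was -0.83 without NPC H3K27me3 replicate 2 and 0.85 without replicate 1.

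Depth and the spread between libraries both limit the smaller changes. At a log2 fold of 1, changes simulated with 1 common dispersion were recovered in 92.9% of cases for H3K4me3, 40.6% for SUZ12, 15.6% for JARID2, 9.2% for MTF2 and 4.2% for H3K27me3. Depth alone does not account for the last, since the H3K27me3 libraries reached 1569812 counts and those of SUZ12 857691, and chi-square per degree of freedom between the NPC H3K27me3 libraries was 6.67.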

Other observations

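The hypothesis at the end of this part was tested with a test chosen after the result was seen, and the values before it come from groups of genes singled out after their values were seen.

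The clustered protocadherins, adhesion genes that give neurons their individual surface identity, had lower SUZ12 and MTF2 in NPC across their clusters. Every family median was below 0 with TMM, library totals, background factors and DESeq2 where any of its TSSs was tested. SUZ12 fell at 14 of 14 Pcdha TSSs (median log2 -2.21, SD 0.654), 15 of 22 Pcdhb TSSs (-1.11) and 19 of 22 Pcdhg TSSs (-1.75). MTF2 fell at 12, 9 and 20 of them (medians -2.12, -0.64 and -1.74; at 11, 3 and 18 with library totals) and JARID2 at 3, 2 and 6. H3K4me3 also fell, at 10 of 14, 14 of 22 and 18 of 22, and rose at 1, 1 and 2. H3K27me3 fell at 5, 9 and 2, with medians of -1.17, -1.14 and -0.86, and at 12, 19 and 15 with library totals. Windows overlapped another at 3, 6 and 11 of these TSSs, so that neighbours share reads there.

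At 164 TSSs SUZ12 and H3K27me3 rose while H3K4me3 fell, 5 of them in the naive pluripotency list (Tbx3, Tfcp2l1, Klf2, Fgf4 and Prdm14), with Zic5 and Zic2 also in the set; the set held 193 TSSs with library totals, 23 with background factors and 9 with DESeq2. MTF2 rose as well at 22 of the 164, including Klf2 and Fgf4. The 164 also held many broadly expressed and small RNA genes, among them Rpl10a, Rpl19, Rps9, Eif4g1, Psmb5 and Snord49a. The number expected of independent lists was not computed. The mirror image, with SUZ12 and H3K27me3 lower and H3K4me3 higher, was found at 317 TSSs, 4 of them in the neural progenitor list (Sox1, Meis2, Cdh2 and Pou3f4), together with Sox11 and Sox4, and the set held 382, 580 and 126 under the same settings.

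By the median log2 change per TSS, H3K27me3, and to a lesser degree MTF2 and SUZ12, fell more on the X chromosome than on the autosomes. The median log2 H3K27me3 change of 461 X-linked TSSs was -0.66, against -0.15 to 0.47 for single autosomes, and 157 (34.1%) fell against 23.2% of autosomal TSSs. The difference between X and autosomes was -0.78 to -0.69 over the 4 library pairs, -0.40 to -0.22 for MTF2 (20.8% against 8.88% fell) and -0.19 to -0.11 for SUZ12 (20.2% against 13.03%). The X share of all H3K27me3 counts was 1.62% and 1.64% in the ESC libraries and 1.499% and 1.32% in the NPC libraries, and 1.65% and 1.72% in the IgG libraries of ESC and NPC. For SUZ12 and MTF2 the X share went the other way. It was 1.443% and 1.447% in ESC and 1.614% and 1.617% in NPC for SUZ12. For MTF2 it was 1.396% and 1.44% in ESC and 1.649% and 1.58% in NPC. The H3K27me3 median of the olfactory receptor list was -0.61, near that of the X-linked TSSs.

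H3K27me3 was above IgG in ESC but not in NPC at 2797 TSSs and in both cell types at 2577. Among those that lost it 194 (6.94%) were above IgG for SUZ12 in ESC and 290 (10.4%) for MTF2, against 865 (33.6%) and 1197 (46.5%) among those that kept it. Of the 1021 TSSs above IgG in NPC alone 62 (6.07%) and 139 (13.6%) were bound in ESC. A higher starting level of H3K27me3 might account for this, so the sets were compared within 10 bins of equal size by ESC level, where the SUZ12-bound share was 26.3% among kept TSSs, 3.79 times that among lost ones (4.84 times without matching). H3K27me3 may thus persist in NPC where SUZ12 was well bound in ESC, although SUZ12 was itself lower there in NPC. Across TSSs, which are not independent replicates, the ESC level of SUZ12 had a Spearman correlation of 0.69 with NPC H3K27me3 (0.652 to 0.727 over library pairs) and of 0.43 with ESC H3K27me3 (0.415 to 0.439), and of 0.43 and 0.52 with the IgG libraries.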
